A study of Mus musculus with 2 samples.

How the data were processed

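The series held 2 libraries made from γδ T cells sorted from mouse thymus. One library came from chromatin immunoprecipitation with an antibody against TCF1, and the other was input chromatin with no antibody. Per the labels, both came from C57BL/6 mice that lack the TCRβ gene, carry a Sox13 transgene and hold an ECFP reporter in 1 Sox13 allele. The cells were CD24-positive with low or no CFP. Per the labels' protocols, 1000000 cells were crosslinked with formaldehyde and sonicated, and the immunoprecipitated DNA was amplified by PCR and selected by size on a gel.

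The deposited file was a list of 104683 genomic intervals for the TCF1 library, with 1 score per interval and no header. The build was mm9, per the submitters' processing notes. The aligner, the peak caller, its threshold, the use of the input library and the meaning of the score are not given in the sources used here. The score as deposited was positive for every interval and moved in steps of 0.25 (100% of scores, relative tolerance 1e-06). The list belonged to 1 library, so it was not a pooled call. All starts lay on a grid of 50 bp and all ends lay 1 bp short of it (100% of each), so ends were read as inclusive. Positions are given counted from 1, and a reading of the ends as exclusive would make each interval 1 bp shorter. No interval was listed more than once (0 duplicates), and 0 neighbouring intervals overlapped. The score grew with width (Spearman rho across intervals 0.80, which are not independent replicates). A second measure, height, was therefore computed as the score divided by the width and multiplied by 50 bp.

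The input library had no processed file and was not used here. The number of reads behind an interval is unknown, so no depth, read-based interval or detection floor is given. With 1 library there was no replicate, and no test between conditions was made. Intervals of confidence given below (95%) are exact Poisson or Clopper-Pearson intervals, or order-statistic intervals of a median. They cover counting error only and treat listed intervals as independent, which clustering makes too narrow.

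The gene table at hand was for GRCm38, another build than mm9. Intervals on 10 chromosomes reached past the last gene of that table. Its coordinates were therefore not used, and no sequence of mm9 was used here. The planned assignment to genes, promoters, exons and introns, the tests of fixed gene lists and the tests of TCF, SOX, RUNX, ETS, E-box, GATA, AP-1 and CTCF motifs need an mm9 annotation or sequence and were not run. The rule fixed before the data were examined then names the 10 highest-scoring intervals on autosomes and X by position and names no gene.

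Density was the number of intervals divided by the distance between the first and the last interval of a chromosome. X was compared with the 19 autosomes by an exact permutation test over the 20 chromosomes, two-sided, whose smallest p is 0.05. Each chromosome in turn took the place of X, and the statistic was its distance from the median of the other 19, or from their mean as an alternative chosen after the data were seen. The relation of density to height across autosomes was tested with 100000 permutations. The distance between midpoints of neighbouring intervals was compared with 100 seeded shuffles of the midpoints within each chromosome's span, without excluding assembly gaps. The shuffle test was one-sided, with a smallest p of 0.0099. Intervals at most 10000 bp apart were joined into domains, and 1 Mb windows were counted on a fixed grid. Intervals above the 99.9th percentile of height were called extreme, and those within 20000 bp of each other formed a run. These limits for domains and runs, the height measure, the relation of density to height and the comparisons of X and of spacing were chosen after the data were seen. The alternatives fixed beforehand were keeping only the upper 50% and the upper 10% by score, leaving out Y, joining intervals within 1 kb and leaving out intervals wider than 10 kb, and ranking by width in place of score.

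The measures were tested on simulated data with 104683 intervals before use. Uniform positions gave a spacing ratio of 1.00, and regional density without local clustering gave 1.00 in 1 Mb windows. Placing a random share of intervals (50% on average) near others gave 0.242. With 104722 intervals, heights on X halved by construction were recovered as a ratio of 0.506, and a density halved by construction as 0.500. The simulated sets were made with the same shuffling and density formula as the measures, so these values check the computation only. They do not test whether the shuffles suit these data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.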

Results

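TCF1, encoded by Tcf7, is an HMG-box transcription factor of T cell development, and SOX13 is an HMG-box factor expressed in developing γδ T cells. The study mapped where TCF1 sat on chromatin in immature γδ thymocytes that carried a Sox13 transgene and were sorted for low or absent CFP, the reporter of the Sox13 locus. The purpose stated for the experiment was a baseline map of TCF1 in cells that are being programmed for effector function. One TCF1 library gave 1 list of intervals. Its input library was not analysed here, so no value has a background measured the same way, and there are no replicates. The number of reads is unknown.

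TCF1 intervals were many and narrow. The list held 104683 intervals on 19 autosomes, X and Y, and together they covered 27.5 Mb of the mm9 genome. The median width was 200 bp, with quartiles at 150 and 300 bp, and the widest interval was 4450 bp. The median score was 134 (95% interval of the median 133 to 135), with quartiles at 70.0 and 248.5. Height, the score per 50 bp of interval, had a median of 34.0 (95% interval 33.9 to 34.1). Its 99th percentile was 77.9, which left few intervals far above the rest. The 1047 intervals in the upper 1% by score held 12.6% of the summed score. With the 105 intervals of extreme height left out, the upper 1% of the remaining list held 7.06% of its summed score.

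The interval density differed about 2-fold between autosomes. Chromosome 11 had the highest density, with 63.5 intervals per Mb (95% Poisson interval 62.1 to 64.9), followed by chromosome 17 with 56.6 (55.1 to 58.2) and chromosome 5 with 52.7 (51.6 to 53.9). Chromosome 1 had the lowest, with 30.2 per Mb (29.4 to 31.0), next to chromosome 3 with 30.9 (30.0 to 31.8) and chromosome 14 with 31.0 (30.0 to 32.0). The mean over autosomes was 42.5 ± 9.88 per Mb (SD over 19 chromosomes). Autosomes with more intervals also had higher ones. The median height ran from 29.8 on chromosome 3 to 37.6 on chromosome 11. Across the 19 autosomes, density and median height were correlated, with Pearson's r = 0.88 (permutation p = 1e-05, the smallest that 100000 permutations can give) and Spearman's rho = 0.82 (permutation p = 5e-05). Without chromosomes 11 and 17, the farthest from the median density, r was 0.88 and rho was 0.79. This was the 1 relation across chromosomes that was computed, so no adjustment was made, but it was chosen after the data were seen. With only the upper 50% of intervals by score r was 0.68, and with only the upper 10% it was 0.014. Choosing by score also narrows the range of heights, so these values are not directly comparable with that for the whole list.

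Intervals on chromosome X were sparser and lower than on every autosome. It held 3200 intervals, or 19.6 per Mb (18.9 to 20.2). Its density was 0.466 times that of the pooled autosomes (95% interval 0.450 to 0.483). The median height on X was 18.9, against a mean of 33.9 ± 2.35 over autosomes (SD over 19 chromosomes). The ratio of the median heights was 0.549 (0.527 to 0.570). X ranked lowest of the 20 chromosomes in both measures. By distance from the median of the other chromosomes, the exact two-sided permutation p was 0.05 for each, the smallest this design allows. By distance from their mean, p was 0.05 for height and 0.1 for density, because chromosome 11 lay at least as far above the others as X lay below, so the test does not single out X by density. In the upper 10% by score the density ratio was 0.187 and the height ratio was 0.911. The score is the height times the width, so a choice by score removes low intervals on every chromosome and, given the lower heights on X, by itself moves the height ratio towards 1 and lowers the density ratio. Neither value shows that the X difference changes with the strength of binding.

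**Figure D1:**
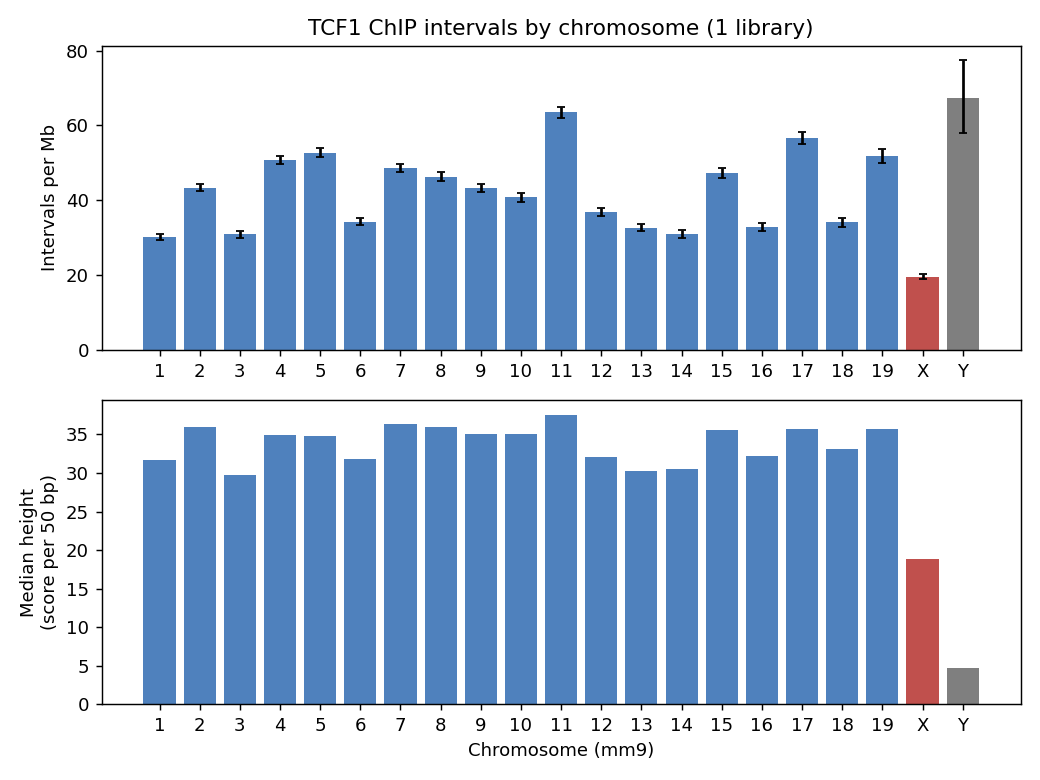
Intervals per Mb (top, bars with 95% Poisson intervals) and median height in score per 50 bp (bottom) for each chromosome of the TCF1 library, with autosomes in blue, X in red and Y in grey. X lies lowest in density, at 19.6 per Mb, and chromosome 11 is the highest of the autosomes, at 63.5 per Mb.

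The ratio of X to autosomal height was nearer 1 in the upper part of the height distribution. At the 10th percentile the height was 11.1 on autosomes and 5.25 on X, a ratio of 0.473, and at the 25th percentile 22.2 against 9.42, a ratio of 0.425. At the 75th percentile it was 46.4 against 33.2, a ratio of 0.716, and at the 99th percentile 78.1 against 67.4, a ratio of 0.863. Among intervals of exactly 200 bp the medians were 32.8 on autosomes and 18.4 on X, so the difference was also present at 1 width. The share of intervals on X fell from 7.63% in the lowest 10% by score (95% Clopper-Pearson interval 7.13 to 8.16%) to 1.25% in the highest 10% (1.05 to 1.48%). Ranked by width, the share moved less, and not steadily. It was 3.74% in the lowest 10% (3.39 to 4.13%) and 2.52% in the highest (2.23 to 2.84%). Widths came in steps of 50 bp, and ties were split by place in the list. The lowest 10% and the next 10% both had a median width of 100 bp, with 3.74% and 3.36% on X. Differences between such groups therefore partly reflect the order of the list and not width.

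Chromosome Y carried 193 intervals, all between positions 29501 and 2902300. Their median height was 4.75, the lowest of any chromosome, and the 90th percentile was 10.1. Of these, 73 began in the last 200 kb of that stretch. The density over the stretch was 67.2 per Mb (58.0 to 77.4).

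**Figure D2:**
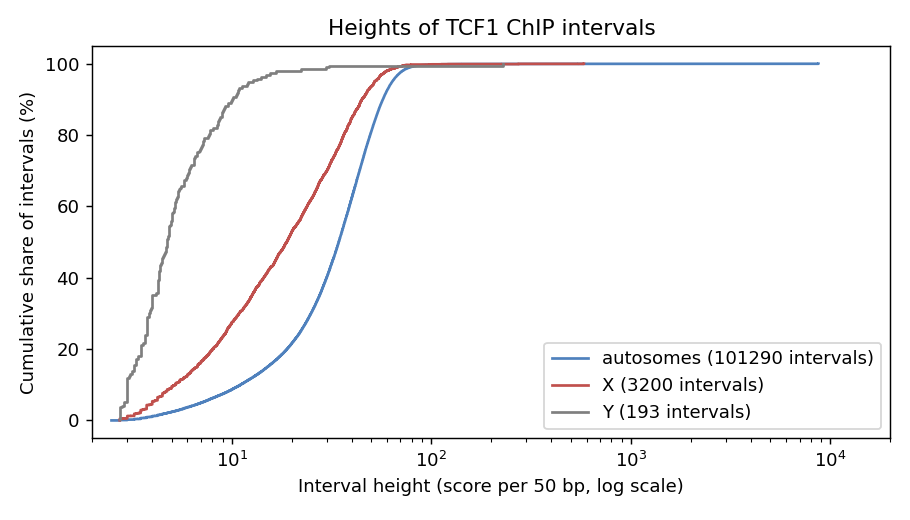
Cumulative share of intervals (percent) against interval height (score per 50 bp, log axis) for autosomes, X and Y. The X curve lies left of the autosomal one, with medians of 18.9 and 34.4, and the Y curve lies farther left, with a median of 4.75.

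Intervals were clustered along the chromosomes. The median distance between the midpoints of neighbours was 8675 bp (95% interval 8550 to 8800). Shuffled within chromosomes, the same number of intervals gave a median of 16314 bp, with 16158 to 16492 over 100 shuffles. The ratio was 0.532 (0.524 to 0.539), below every shuffle (one-sided permutation p = 0.0099, the smallest that 100 shuffles can give). Shuffled within 1 Mb windows, which keeps regional density, the expected distance was 11335 bp and the ratio was 0.765 (0.754 to 0.776). Within 100 kb windows the ratio was 0.880 (0.867 to 0.892).

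**Figure D3:**
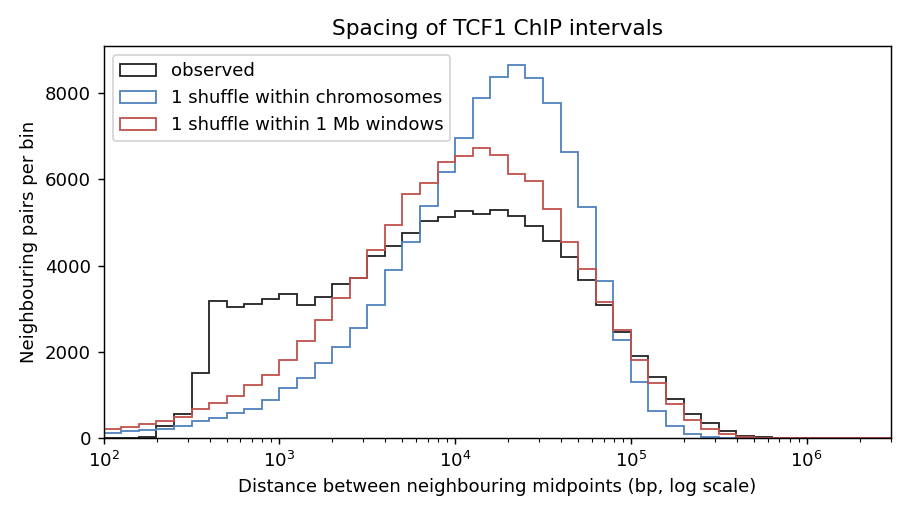
Number of neighbouring pairs per bin against the distance between their midpoints (bp, log axis), as observed (black), after 1 shuffle within chromosomes (blue) and after 1 shuffle within 1 Mb windows (red). The observed distances, with a median of 8675 bp, hold more pairs near 1000 bp than either shuffle.

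The densest part of the map lay on chromosome 10. The window from 79000001 to 80000000 held 418 intervals and the next, from 80000001 to 81000000, held 417. The median over 2589 windows of 1 Mb on autosomes and X was 26, and the fullest window in each of 100 shuffles held 79 to 96. Windows on chromosome 7 (52000001 to 53000000, 282 intervals), chromosome 4 (140000001 to 141000000, 267), chromosome 17 (27000001 to 28000000, 265) and chromosome 11 (115000001 to 116000000, 260) followed. The fullest 10% of windows (259) held 34.3% of the intervals. After joining intervals within 1 kb, the fullest window held 224, so part of the count came from closely spaced neighbours.

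Joining intervals at most 10000 bp apart gave 48579 domains, of which 30120 (62.0%) held a single interval. The 1168 domains with 10 or more intervals held 21937 of them (21.0%), and 3 domains held more than 100. The domain with the most intervals, on chromosome 10 from 79316151 to 79565350, held 150 over 249 kb, and intervals covered 16.9% of it. A second on the same chromosome, from 80676101 to 80896550, held 132. The next were on chromosome 17 from 46570601 to 46873800 (104 intervals), chromosome 5 from 125483751 to 125770250 (98) and chromosome 7 from 19890101 to 20081600 (93). The number and borders of domains depend on the joining distance, which has no counterpart in the sources used here. Which genes lie in these regions was not analysed here.

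The highest-scoring intervals stood far outside the rest of the list. The highest, on chromosome 17 from 39979751 to 39984200, had a score of 775344, which was 3.41% of the summed score. Its height of 8712 was 256 times the median. Its neighbour, from 39984701 to 39985900, had a score of 161425 and a height of 6726. Of the other 8 among the 10 highest on autosomes and X, 2 were on chromosome 16, from 57391301 to 57391950 (score 45231) and from 11143851 to 11144450 (37412). Chromosome 11 held 3, from 108872851 to 108873500 (43385), from 3093001 to 3093550 (30184) and from 3068701 to 3069050 (24435). The remaining 3 were on chromosome 3 from 5860151 to 5861000 (27853), on chromosome 5 from 147072351 to 147073100 (25311) and on chromosome 17 from 36368001 to 36368550 (20469). These 10 intervals had heights from 1638 to 8712, or at least 48.2 times the median height. No input value or repeat annotation stands beside them, so their scores do not separate TCF1 binding from sequence that the genome holds in many copies, such as ribosomal DNA.

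**Figure D4:**
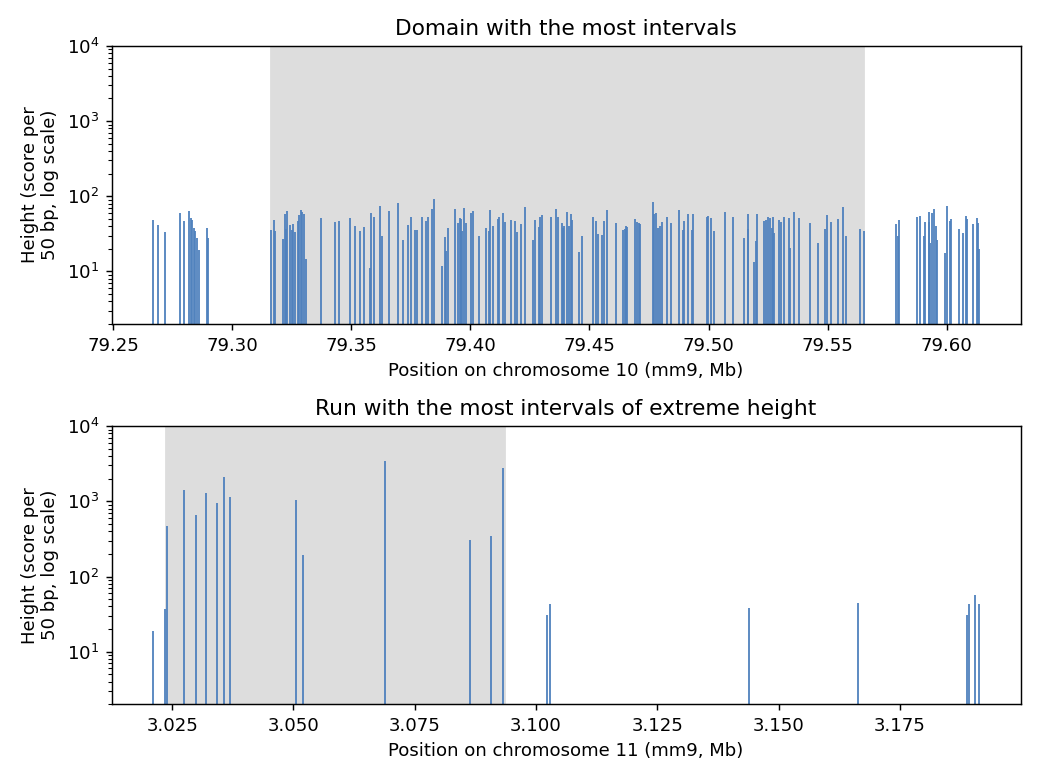
Interval height (score per 50 bp, log axis) against mm9 position (Mb), with 1 line per interval, for the domain with the most intervals on chromosome 10 (top) and the run with the most intervals of extreme height on chromosome 11 (bottom), both shaded. The domain holds 150 intervals, with a summed score of 49.9 per 50 bp covered, against a median interval height of 34.0 in the whole list. The run holds 13 intervals with a median height of 1045.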

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

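The alternatives that left out extreme heights, shuffled within windows (with or without joining), kept 1 width or used the mean in the permutation test of X were chosen after the data were seen. Of 62 alternative values, 35 stayed close to the main value, 26 moved and 1 was weaker, and none changed direction. Part of the 35 could not have moved. No interval was wider than 10 kb, and leaving out Y cannot alter values computed from X and autosomes alone. The tally is therefore no measure of robustness. The weaker one was the permutation p of the X density, 0.05 by distance from the median of the other chromosomes and 0.1 by distance from their mean. Close meant within 1.5 times for counts of intervals and shares of score, inside the 95% interval of Fisher's transformation for r, on the same side of 0.05 for a permutation p (0.05 itself counted as passing), and inside the counting interval otherwise. The upper 50% by score held 52327 intervals and the upper 10% held 10458, by construction. The X to autosome density ratio of 0.466 became 0.283 in the upper 50%, 0.187 in the upper 10% and 0.492 after joining intervals within 1 kb. The height ratio of 0.549 became 0.836 and 0.911 in the upper 50% and 10%. A choice by score removes low intervals everywhere, which, given the lower heights on X, by itself moves both ratios in these directions. The spacing ratio of 0.532 became 0.422 and 0.470 in these 2 sets, 0.660 after joining within 1 kb, and 0.765 and 0.880 when shuffled within 1 Mb and 100 kb windows. With joining and windows combined it was 0.889 and 0.969. Joining removes the shortest distances, and the cause of the other shifts in spacing was not tested. Leaving out Y (104490 intervals) or the 105 extreme heights (104578) moved none of these ratios outside its counting interval, and no interval was wider than 10 kb, so that alternative changed nothing. No paired analysis was possible because there was 1 ChIP library. Alternatives that concern genes, gene location or motifs were not run, for want of an mm9 annotation or sequence. The unknown read depth limits all statements on low intervals, and a missing interval does not show that TCF1 was absent.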

Other observations

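Some intervals of extreme height lay close together, but most had no other within 20 kb. Of the 105 intervals above a height of 132.8 (3.90 times the median), 39 lay within 20 kb of another one, and they formed 11 runs. Some of the others lay near one another beyond this limit. Examples are those on chromosome 8 from 19698751 to 20020450 and those starting at 90151401 and 90173751 on chromosome 1. One run on chromosome 11, from 3023801 to 3093550, held 13, with a median height of 1045 against 40.4 over the 10 listed intervals within 100 kb of it. Others lay on chromosome 17 from 13743351 to 13745750 (5 intervals), on chromosome 10 from 57686451 to 57695850 (3), on chromosome 1 from 135279101 to 135283900 (3), on chromosome 8 from 56199151 to 56208700 (3), and at the end of the X intervals from 166434251 to 166443550 (2). On chromosome 1 the first interval of the run was 1550 bp wide with a height of 205, and the 28 listed intervals within 100 kb had a median of 38.8.

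All tests in the following paragraphs were chosen after the result was seen, except the comparison of all 105 extreme intervals with the rest of the upper 1% by height near chromosome ends, the joining of intervals within 1 kb, and the combined test of clustering. Joining within 1 kb was fixed beforehand as an alternative, but its use against an explanation of the clustering was chosen after its value was seen. The limit for the combined test was written before its value but after the values for its 2 parts.

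For the extreme heights, strong binding at sites placed like the rest of the upper 1% by height is argued against as the whole cause. Nearness to an end does not show whether an interval reflects binding, so strong binding at sites near ends stays open. Of the 105 extreme intervals, 23 (21.9%) lay within 1 Mb of the first or last interval of a chromosome, against 20 of the other 942 intervals in the upper 1% by height (2.12%), and 10000 draws of 105 from those 942 gave at most 9 (permutation p = 0.0001, the smallest they can give). The run on chromosome 11 gave 13 of the 23, and without it 10 of 92 remained, against at most 9 in draws of 92. With each run counted as 1 place, 9 of 77 places lay near an end, against at most 7 in 10000 draws from the 882 places of the others. Sequence present in many copies is an open explanation, and the gathering into runs does not decide it. Distances after joining were taken between starts. After joining extreme intervals within 1 kb, 23 of 94 lay within 20 kb of another. Draws from the rest of the upper 1%, joined alike, gave at most 10 (11 of 82 against at most 9 without the chromosome 11 run). After joining within 10 kb, 3 of 80 did, against a median of 0 and at most 6 in the draws (permutation p = 0.0078). Without the chromosome 11 run none did. Every run other than that on chromosome 11 spanned at most 9.55 kb, so this joining had to make each of them 1 interval. The fall in the count therefore shows nothing about its cause. Whether strong regions were listed as several intervals stays undecided, and no sequence was searched. The labels give a Sox13 transgene, and extra copies of its sequence could also give a run. Whether the run on chromosome 1 or any other of the 11 runs covers Sox13 sequence was not checked. Such copies cannot be told apart here from other sources of many copies. Neither the mm9 position of the transgene's sequence nor a library without the transgene was used.

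For the sparser and lower intervals on X, low density alone is argued against. In 1 Mb windows with 20 to 39 intervals, the median height was 18.9 on X (58 windows) and 25.1 to 31.7 on the 19 autosomes. It was also below every autosome in windows with 10 to 19 intervals (14.3 against 17.6 to 27.4), over only 6 X windows with 40 to 79 (31.7 against 32.9 to 36.7), and over 11 X windows with 5 to 9 (9.36 against 10.8 to 22.5 on the 14 autosomes with at least 3 such windows). The X to autosome ratio of these window medians, pooled over autosomes, was 0.566, 0.736, 0.656 and 0.906 from the emptiest class to the fullest. Over all windows with 5 or more intervals it was 0.554, and with the autosomal windows weighted to the 4 density classes of X it was 0.744. Density thus went with part of the gap, but not in the emptiest class. A single X copy in some or all of the cells is a candidate explanation that stays open. It would lower all X heights by about 1 factor, whereas the X to autosome ratio rose by 0.359 between the 25th and the 90th percentile. That difference would count against it only if the score were proportional to the amount of DNA, which is not stated. The sex of the mice is not in the labels. The list held 193 intervals on Y, with a median height of 4.75. They would point to Y DNA in at least part of the pool only if their reads were placed correctly, which was not checked. Lower occupancy of X by TCF1 was not tested.

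For the clustering, regional density on the scale of 1 Mb alone is argued against, provided that intervals could lie anywhere within a window. The spacing ratio was 0.765 when intervals were shuffled within 1 Mb windows, below every shuffle. The shuffles here and below could place intervals in assembly gaps or other sequence that yields none, which by itself lowers the ratio. How far it did so was not tested. Regions listed as several intervals at most 1 kb apart are argued against as the whole cause. After joining intervals within 1 kb and shuffling within chromosomes, the ratio was 0.660. Regions split at wider gaps were not joined and stay open. Regional density on the scale of 1 Mb combined with splits of at most 1 kb is argued against too, under the same condition and by less. Joined intervals shuffled within 1 Mb windows, with more than 1 kb kept between them, gave a ratio of 0.883 (0.873 to 0.897), below every shuffle. Within 100 kb windows the same ratio was 0.978 (0.967 to 0.993), so little was left beyond density on that scale, and such windows keep part of the clustering itself. Uneven shearing or recovery of open chromatin, which the input library would show, was not tested, and clustered binding of TCF1 stays open beside it.

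The list was sorted neither by position nor by score. Across intervals, the place in the list had a Spearman rho of -0.45 with the score and of -0.75 with the width. The first 100 intervals had a median width of 450 bp and a median height of 29.05, below the 34.0 of the whole list, and 8 of them were on Y.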
